A study of Mus musculus with 37 samples.

How the data were processed

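The series holds CAGE libraries of 37 mouse liver samples. Per the labels' protocols, total RNA was extracted with a mirVana kit, cDNA was made with random primers, capped molecules were captured, and barcoded 5′ linkers were added before cutting with EcoP15I. The submitters' processing notes name CASAVA 1.8, BWA 0.5.9 and the builds hg19, GRCh37 and mm9, without a role for any of them. How peaks were called and which method gave the differences is not given in the sources used here.

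The authors deposited 1 table of 49096 peaks and 48 columns without a header line. It gives for each peak its position in mm9, a class, gene and transcript names, a tag count per peak, a log2 difference and an adjusted p-value. The authors' tag count is a whole number per peak, taken as the tags summed over libraries. The meaning of the authors' log2 column and p-value column was read from the values. In peaks of under 2048 tags the largest absolute difference rises by 0.954 per doubling of the tags, as a log2 ratio does. The p-value is taken as adjusted, since 22504 values under 1 tie exactly with another. The authors' method of adjustment is not given in the sources used here, nor are the 2 groups compared or the direction. Start positions counted from 0 in the file are printed from 1.

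A further 37 columns hold values per library without names. No column could be matched to a sample, so these 37 columns were not used in any step. In a first look at the file their first lines and ranges were seen before they were set aside, and nothing was taken from them. Before the data were examined, 8 comparisons between groups, a test of promoter switching and a test of the share of signal outside promoters had been planned as fits to library values. None could be run, and the analysis instead describes the authors' own comparison. Depth per library is for the same reason not given. Replicates, batches and the spread between samples could not be examined.

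A gene was represented by its Coding peak with the most tags. Of the Coding peaks, 110 without a gene name and 71 with several names were left out, which left 11956 genes. A peak or gene counts as positive or negative where its adjusted p is under 0.05. The class was tested against GENCODE vM1 on the NCBIM37 genome, which is mm9, using protein-coding transcripts. Long non-coding RNAs were matched to the peak with the most tags within 100 bp of an annotated start on the same strand.

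The 30 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Abcb4, the 5 genes with the largest positive and the 5 with the largest negative difference among called genes, up to 2 members per sign from each list, or the member with the most tags where none was called, and the sex-linked genes. Some single genes that the rule or a count covers are not reported here. Its minimum of 5 CPM in a group could not be applied without library values and was replaced by the same rate over the summed tags, which is 1630 tags, for the largest differences. The planned list test also needed library values. In its place limma 3.58.1 (R 4.3.3) cameraPR compared a signed score of a list's genes with that of all other genes, for the 28 lists with at least 3 measured members, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. The score is the normal quantile of an upper bound on the unadjusted p. That bound is the adjusted p times its rank over 49096, and holds if the authors adjusted by Benjamini-Hochberg over all peaks, which is an assumption. Counts "adjusted over the list alone" apply Benjamini-Hochberg to these bounds within a list. A correlation between genes could not be estimated without library values, so it is not known which list calls would hold with one.

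Classes were compared by Fisher's exact test. Repeated sequence was measured as the share of 20-mers within 100 bp of a peak's centre that occur 10 or more times in the genome, and a peak with a share of at least 0.5 counted as repeat. Called and uncalled peaks were compared for repeats among peaks with 50 or more tags. Tests were written in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and pysam 0.24.0, and figures in matplotlib 3.10.9. On simulated scores for the same 11956 genes and 28 lists, the list test called 2 of 280 unchanged lists and recovered 60 of 60 lists shifted by 1.5. The scores were drawn independently, so this does not show how the test behaves where members of a list are correlated. On 49096 simulated p-values the bound was never below the true p, which holds by construction where Benjamini-Hochberg was used, as it was there.

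Alternatives tried after the data were examined were thresholds of 0.01 and 0.001, minimums of 100 and 1000 tags, other peaks per gene, a correlation of 0.05, other scores, and 10000 random lists matched on tags in 20 bins.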

Results

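Capped 5′ ends of RNA were sequenced by CAGE, which marks where transcription starts, in 37 mouse liver samples of the Mdr2 knockout model. Mdr2 is the product of Abcb4, the canalicular transporter that moves phospholipid into bile, and livers without it develop chronic inflammation and then tumours. By their labels, 6 samples were wild type, 3 were inflamed liver, 4 were adenoma, 16 were of the group with a low share of carcinoma and 8 of the group with a high share. The wild-type and inflamed samples were all male, and the 28 lesion-bearing samples were 7 female and 21 male. The table held 49096 CAGE peaks with 325970479 tags in all, from 10 to 25518587 per peak with a median of 206. Its 37 columns of values per library carried no names and were not used, so no depth, mean or error per sample is given here, and the groups could not be compared with each other from library values.

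The table also held a log2 difference and an adjusted p-value per peak for 1 comparison between 2 groups that it does not name. All differences below are from that comparison, so each is given as positive or negative and no group is called higher. Neither the number of libraries nor the spread behind a difference is stated in the file, and these values therefore carry no error of their own.

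Abcb4, the gene named as knocked out, was the most extreme of all peaks by adjusted p. Its main peak on chromosome 5 (8893568 to 8893981, plus strand, mm9), at the annotated start of the gene, had a log2 difference of -10.76 with an adjusted p of 1.4e-32 in the authors' deposited table. An adjusted p under 0.05 was given to 4092 peaks in the authors' deposited table, of which 2275 were positive and 1817 negative. Represented by the Coding peak with the most tags, 890 of 11956 genes were positive and 291 negative at that threshold in the authors' deposited table, and the median over all genes was 0.11.

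The largest positive differences among called genes with at least 1630 tags included a transporter, a secreted peptide and adhesion proteins. In the authors' deposited table Vmn2r3, a vomeronasal receptor gene, stood at 13.05, Pcdh17, a protocadherin, at 10.59, and Slc7a11, the cystine transporter, at 10.33. Tff3, a secreted trefoil peptide, followed at 9.20 and Gldn, which encodes gliomedin, at 9.15 in the authors' deposited table. Their adjusted p ran from 5.7e-13 for Tff3 to 2.7e-06 for Vmn2r3 in the authors' deposited table. In peaks of under 2048 tags the largest absolute value rose by 0.954 per doubling of tags, so tags limit how large a difference can be there. Of these genes only Pcdh17, on 1899 tags, lies in that range. The order of these genes may depend on their tags too, which was not tested. Vmn2r3, on 2621 tags, had the largest positive value of the 1331 positive peaks in the same doubling of tags, and Tff3, on 86911, that of 210, in the authors' deposited table. On the negative side the authors' deposited table put Camk1d, a calcium-dependent kinase, at -6.71, 2810007J24Rik at -5.69, Elovl3, a fatty acid elongase, at -5.29 and Mup21, a major urinary protein, at -5.25, after Abcb4. The second peaks by tags of Camk1d, at 0.22 (adjusted p = 0.99), and of 2810007J24Rik, at -1.76 (0.19), did not pass in the authors' deposited table.

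Genes of cell division and of the fetal liver and liver cancer were mostly positive. Of 25 measured cell cycle genes, 19 were positive and none negative in the authors' deposited table, and 24 were positive when adjusted over the list alone. Kif20a, a mitotic kinesin, stood at 7.21 and Foxm1, a transcription factor of the cell cycle, at 6.51 in the authors' deposited table. The second peak of Kif20a by tags, with 34 tags against 1447, stood at 0.67 (adjusted p = 0.99) in the authors' deposited table. Of 17 measured oncofetal and carcinoma-associated genes, 12 were positive and none negative in the authors' deposited table, and 14 were positive when adjusted over the list alone. Igf2, the fetal growth factor, stood at 9.12 in the authors' deposited table, just below Tff3. Both lists were positive against all other genes by limma's cameraPR with a preset correlation of 0.01, at adjusted p of 7.8e-23 and 8.1e-20. Among 14 p53 targets 5 were positive and 7 when adjusted over the list alone (cameraPR adjusted p = 4.4e-05), with Gdf15 at 5.26 and Cdkn1a, an inhibitor of cyclin-dependent kinases, at 4.67 in the authors' deposited table.

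Some inflammatory and matrix genes were positive, and none of those measured in the 4 lists was negative over all peaks. Of 16 interferon response genes 9 were positive, and 11 when adjusted over the list alone (cameraPR adjusted p = 1.4e-07), with Usp18 at 4.37 and Ifi44 at 4.29 in the authors' deposited table. Of 19 NF-kB and chemokine targets 6 were positive on either count (cameraPR adjusted p = 0.00028), among them the chemokines Ccl2 at 4.42 and Cxcl10 at 3.83 in the authors' deposited table. Of 19 fibrosis and stellate cell markers 6 were positive, and 9 when adjusted over the list alone (cameraPR adjusted p = 0.00070), with Tagln at 3.14 and Col1a1, a collagen chain, at 3.09 in the authors' deposited table. Of 21 acute phase genes 3 were positive and none negative, and 8 were positive and 2 negative when adjusted over the list alone. Lcn2, which encodes lipocalin, stood at 4.86 and Hpx, which encodes hemopexin, at 3.26 in the authors' deposited table, where the second peak of Hpx by tags stood at 1.73 (adjusted p = 0.21). The list passed at an adjusted p of 0.030 by cameraPR but not with a preset correlation of 0.05 (adjusted p = 0.10).

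Markers of other cell types did not move as 1 block. Of 14 macrophage markers 3 were positive on either count, with Ms4a7 at 5.44 and Gpnmb at 5.07 in the authors' deposited table. The list passed cameraPR (adjusted p = 0.031) but lost the call under 4 alternatives, among them a preset correlation of 0.05 (adjusted p = 0.092). Of 14 endothelial markers 3 were positive on either count, with Cd34 at 4.24 and Cdh5, an endothelial cadherin, at 2.34 in the authors' deposited table, and the list did not pass (adjusted p = 0.31). Of 10 cholangiocyte markers 2 were positive and 1 negative, and 4 and 2 when adjusted over the list alone (adjusted p = 0.31). Spp1, which encodes osteopontin, stood at 3.63, Prom1 at 3.24 and Muc1 at -3.07 in the authors' deposited table. No marker of T and NK cells (13 measured), B and plasma cells (4), neutrophils (7) or erythroid cells (3) passed over all peaks in the authors' deposited table. Adjusted over the list alone, 1 erythroid marker was positive and no marker of the other lists passed, and the bound on the unadjusted p was under 0.05 for 2 T and NK cell markers, 1 erythroid marker and no other. None of these lists passed cameraPR, with adjusted p of 0.37 for T and NK cells, 0.31 for B and plasma cells, 0.75 for neutrophils and 0.42 for erythroid cells. The markers of these lists with the most tags, Cd3g at 0.34, Igj at -0.52, Ngp at 0.33 and Hbb-b1 at -1.47, did not pass in the authors' deposited table. The adipocyte list (3 measured) had 1 positive member on either count, Fabp4 at 6.09 in the authors' deposited table (list adjusted p = 0.18). Among 3 mesothelial markers Upk1b was negative at -3.33 on either count in the authors' deposited table (list adjusted p = 0.031), and no pancreas marker was measured.

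**Figure D1:**
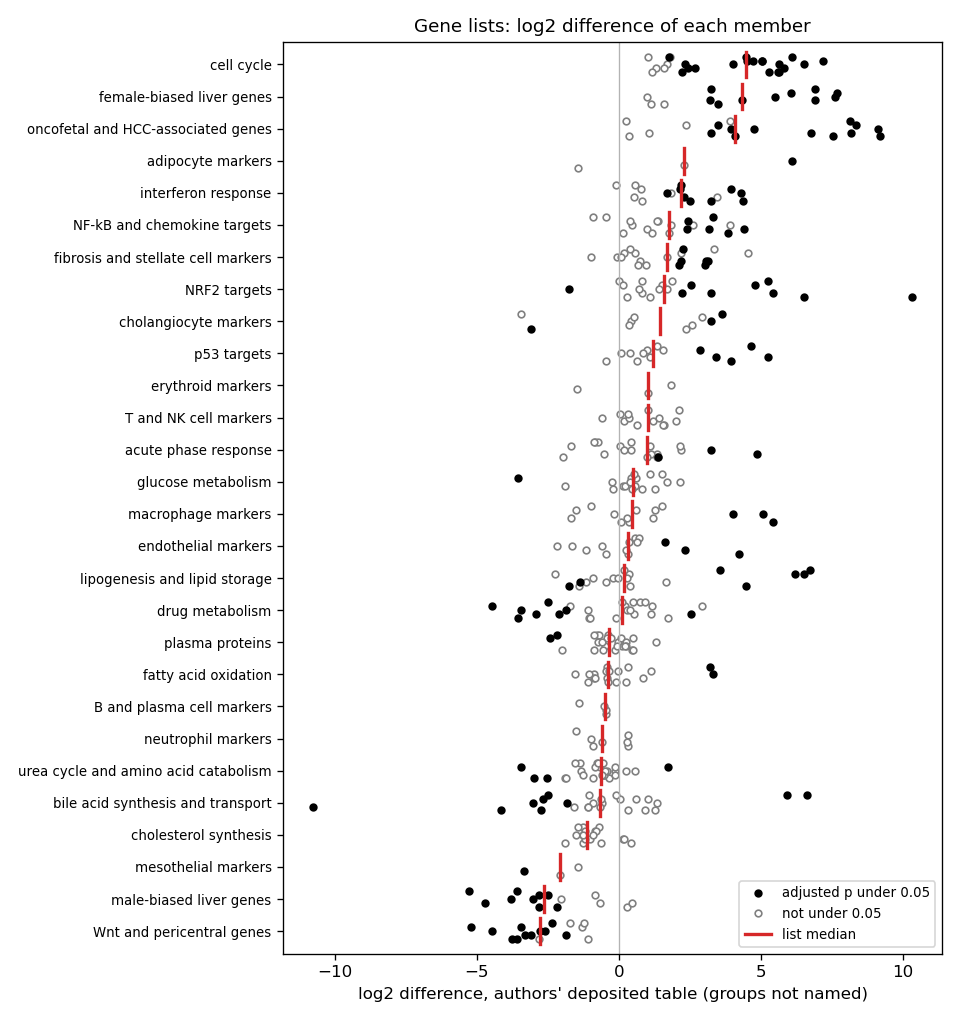
Each point is 1 gene of a list, placed by the log2 difference of its main peak in the authors' deposited table (horizontal axis, log2 units, groups not named), with filled points for an adjusted p under 0.05 and a red line at the list median. The cell cycle list has the highest median (4.47) and the Wnt and pericentral list the lowest (-2.79).

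Genes of the zone around the central vein, where Wnt signalling is active, were mostly negative. Of 16 measured Wnt and pericentral genes 11 were negative and none positive, and 14 were negative when adjusted over the list alone (cameraPR adjusted p = 9.8e-18). Tbx3, a transcription factor, stood at -5.21 and Cyp2e1 at -4.45 in the authors' deposited table. In bile acid synthesis and transport 7 of 25 genes were negative and 2 positive, and 9 and 4 when adjusted over the list alone (cameraPR adjusted p = 0.0018). The list holds Abcb4 itself, and without it the list did not pass (adjusted p = 0.063). Cyp8b1, which sets the ratio of bile acids made, stood at -4.13, and 2 basolateral exporters were positive, Ostb at 6.64 and Abcc4 at 5.92, in the authors' deposited table. In drug metabolism 7 of 25 genes were negative and 1 positive, and 8 and 3 when adjusted over the list alone. Of its measured members 4 are also in another list, among them Cyp2e1, which is counted with the pericentral genes above. Cyp2c29 stood at -3.55 and Gstm1 at 2.55 in the authors' deposited table. That list was negative by cameraPR (adjusted p = 0.027) although its median was 0.10, and the call was lost with a preset correlation of 0.05 (adjusted p = 0.10), with ranks (0.36) and against random lists of like tag counts (0.87).

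In the urea cycle and amino acid catabolism 3 of 28 genes were negative and 1 positive, and 4 and 1 when adjusted over the list alone (cameraPR adjusted p = 0.00038). Oat stood at -3.44, Got1 at -2.99 and Sdsl at 1.75 in the authors' deposited table. Oat is also in the Wnt and pericentral list. The second peak of Sdsl by tags stood at 0.57 (adjusted p = 0.56) and that of Pklr, a glucose metabolism gene, at -1.01 (0.68) in the authors' deposited table. None of 18 cholesterol synthesis genes passed on either count, and for 2 of them the bound on the unadjusted p was under 0.05, while the list was negative as a whole with a median of -1.11 (cameraPR adjusted p = 0.0068). In lipogenesis and lipid storage 5 of 19 genes were positive and 2 negative, and 5 and 4 when adjusted over the list alone (adjusted p = 0.083). The positive members included the lipid droplet genes Cidec at 6.73 and Plin4 at 6.53, and the negative ones were Me1, malic enzyme, at -1.74 and Mlxipl at -1.35, in the authors' deposited table. Fatty acid oxidation had 2 positive members of 19, Fgf21 at 3.31 and Cyp4a14 at 3.22, in the authors' deposited table (list adjusted p = 0.77). Glucose metabolism had 1 negative member of 18, Pklr at -3.56 in the authors' deposited table (list adjusted p = 0.31), and plasma proteins had 2 of 26, F11 at -2.42 and C6 at -2.18, in the authors' deposited table (list adjusted p = 0.22). These 3 lists gave the same counts when adjusted over the list alone. Of 20 NRF2 targets 8 were positive and 1 negative, and 12 and 1 when adjusted over the list alone (cameraPR adjusted p = 9.9e-09), led by Slc7a11 and by Gsta1 at 6.52 in the authors' deposited table.

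Genes known to differ between the sexes in mouse liver moved apart. Of 14 male-biased genes 9 were negative and none positive, and 10 were negative when adjusted over the list alone (cameraPR adjusted p = 1.2e-09). Elovl3 stood at -5.29 (adjusted p = 2.3e-06) and Hsd3b5, on 170 tags, at -4.71 (0.016) in the authors' deposited table. Of 13 female-biased genes 10 were positive on either count and none negative (cameraPR adjusted p = 1.8e-09). Cyp2a4 stood at 7.69 (adjusted p = 3.4e-07) and Sult2a2, on 653 tags, at 7.60 (0.033) in the authors' deposited table. The Y-linked genes Ddx3y (-1.43), Uty (-1.09), Eif2s3y (-1.26) and Kdm5d (-0.84) were negative and none passed, with a lowest adjusted p of 0.31, in the authors' deposited table. Xist, which is expressed in females, stood at 2.07 with an adjusted p of 0.60 in the authors' deposited table. Of the male-biased and female-biased members measured, 4 and 2 are also in another list. Copies of Mup, Cyp2a, Gsta and Sult2a genes are similar in sequence, so tags could be split among them and single members are uncertain.

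Of the 27 long non-coding RNAs listed, 15 had a peak within 100 bp of an annotated start on the same strand, and 3 of these were positive and none negative in the authors' deposited table. H19, the imprinted RNA beside Igf2, stood at 11.10 with an adjusted p of 1.4e-13 on 217378 tags in the authors' deposited table. Pvt1 stood at 2.91 (adjusted p = 0.022) and Airn at 2.50 (0.047), while Malat1 at -0.84 and Neat1 at 0.57 did not pass, in the authors' deposited table. Under the file's own gene names only 1500012F01Rik was measured, at 0.62 (adjusted p = 0.44) in the authors' deposited table.

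The classes of peaks differed in the sign of their calls. Coding peaks lay within 100 bp of a protein-coding transcript start on the same strand and Distal peaks at least 5003 bp from any such start. Proximal peaks lay at least 101 bp from such a start on the same strand, but only 12740 of the 20556 lay within 5000 bp of one on either strand, and the farthest lay 836732 bp away. Of all tags 82.1% lay in Coding, 9.43% in Proximal and 8.49% in Distal peaks. Among Coding peaks 1021 were positive and 354 negative in the authors' deposited table, against 514 and 794 of the Proximal and 740 and 669 of the Distal peaks. The positive share was 74.3% for Coding (95% Wilson interval 71.9 to 76.5), 39.3% for Proximal (36.7 to 41.97) and 52.5% for Distal (49.9 to 55.1), where the intervals cover counting error only and treat peaks as independent. Each of the 3 pairs of classes differed by Fisher's exact test, two-sided and adjusted over the 3 tests, with odds ratios of 4.46 (Coding against Proximal, adjusted p = 9.8e-76), 2.61 (Coding against Distal, 1.1e-32) and 1.71 (Distal against Proximal, 5.1e-12). Peaks of 1 gene are not independent, so these p-values are too small.

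**Figure D2:**
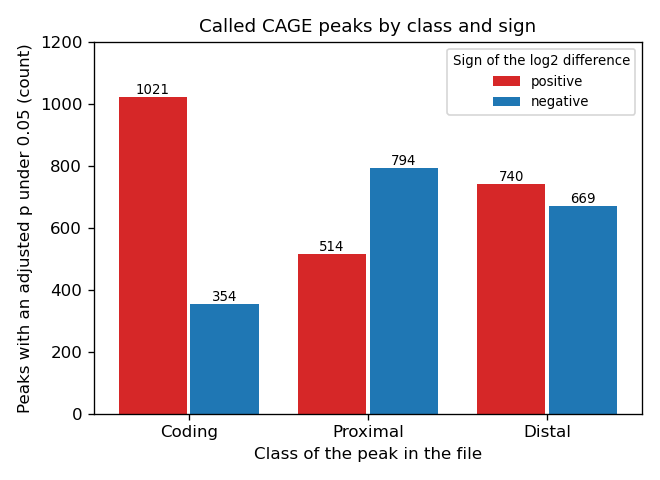
Bars count the peaks with an adjusted p under 0.05 in the authors' deposited table (vertical axis, peaks) in each class of the file (horizontal axis), by sign of the log2 difference. Coding has 1021 positive and 354 negative peaks, while Proximal has 514 and 794.

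Outside the Coding class, the peaks with the largest differences among those with enough tags were chosen after their values were seen. A Distal peak on chromosome 3 (45018417 to 45018449, plus strand), in no annotated gene, stood at 13.99 in the authors' deposited table. A Proximal peak on chromosome 17 (37332455 to 37332458, plus strand), inside Ubd, stood at 12.20 in the authors' deposited table. On the negative side a Distal peak on chromosome 8 (125696743 to 125696750, plus strand), inside Gm20388, stood at -9.51 in the authors' deposited table. A Proximal peak on chromosome 15 (79728185 to 79728193, minus strand), on the strand opposite to Apobec3, stood at -8.66 in the authors' deposited table.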

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

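No paired analysis was possible because the columns of library values carry no names and so no replicate numbers. None of the alternatives planned for the group comparisons, promoter switching, the share of signal outside promoters and the list tests was run, since each refits library values. All alternatives here were chosen after seeing the data. At an adjusted p under 0.01 and under 0.001, positive peaks numbered 1339 and 715, negative peaks 905 and 418, positive genes 570 and 336, and negative genes 139 and 57. With 1000 or more tags there were 972 positive and 571 negative peaks. The positive share of Coding peaks was 78.8% and 83.7% at the 2 stricter thresholds. For Proximal peaks it was 42.7% and 45.6%, and 41.97% and 42.9% with 100 and 1000 or more tags. For Distal peaks it was 56.4% and 59.0% with those tag minimums. The share of all tags outside Coding peaks, 17.9%, was 16.6% without the 10 peaks with the most tags and 16.99% without mitochondrial peaks. Of the list tests, acute phase was no longer called with a correlation of 0.05 (adjusted p = 0.104) or with the log2 difference as score (0.311). Macrophage markers were not called with a correlation of 0.05 (0.0918), ranks (0.137), the log2 difference (0.121) or matched random lists (0.194). Drug metabolism was not called with a correlation of 0.05 (0.104), ranks (0.364) or matched random lists (0.874). Bile acid genes were not called without Abcb4 (0.0631), and cholangiocyte markers were called against matched random lists (0.0138). With 100 or more tags the adipocyte list had too few members to test. The other list calls kept their direction and side of the threshold under the alternatives run. The cause of these changes was not tested, except that stricter thresholds and minimums test or pass fewer peaks by construction. Of the 65 named genes 6 were no longer called at 0.01. Of the 11 with a second Coding peak, 5 kept their call, 5 lost it (Kif20a, Hpx, 2810007J24Rik, Pklr and Sdsl), and Camk1d changed sign to 0.22.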

Other observations

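The tests in this part were chosen after the results were seen, except the test of the region around Abcb4, whose prediction was written before its result.

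Gene families were also picked by symbol. Of 48 replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, 32 were positive and 0 negative, against 7.21% positive among other genes (Fisher's exact test, odds ratio 25.8, adjusted p = 1.1e-23). Of 13 major urinary protein genes, which are pheromone carriers with near-identical copies, 0 were positive and 8 negative (odds ratio 65.9, adjusted p = 2.2e-09), and of the negative ones Mup1 and Mup7 are also in the male-biased list. The family tests count each gene as independent, and tags could be split among such copies, so their p-values are too small. Of 24 collagen genes 8 were positive (adjusted p = 0.0019), 4 of them already counted among the fibrosis markers, and 2 were negative (adjusted p = 0.33). None of 73 mitochondrial ribosomal protein genes was positive (adjusted p = 0.026) or negative (adjusted p = 0.81). Cytochromes P450 had 12 of 61 negative (adjusted p = 2.3e-07) and 8 positive (0.34), of which 9 and 4 are also in a gene list. Chemokines had 7 of 22 positive (0.0053), 2 of them also in a gene list, and 0 negative. Solute carriers had 14 of 219 negative (0.0054) and 14 positive (0.95), of which 3 and 1 are also in a gene list. Serpins had 7 of 29 positive (0.022) and 2 negative (0.35). The adjustment is over 34 tests of 17 families, and 8 of the tests passed. Among 57 genes with at least 2 called Coding peaks, 6 had called peaks of both signs, among them Smarca2, Zbtb20 and Blvrb. In the authors' deposited table the 2 called peaks of Smarca2, a chromatin remodelling ATPase, stood at -1.66 and 1.82 on 8303 and 7188 tags (adjusted p = 0.012 and 0.044). The positive peak of Zbtb20 had an adjusted p of 0.047 there. Only Blvrb kept both signs at an adjusted p under 0.01, at 2.53 and -2.38 (adjusted p = 0.0051 and 0.0031) in the authors' deposited table. Among peaks with at least 10 and under 50 tags, 3 were called positive and 85 negative.

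A first hypothesis concerns the direction of the comparison. Positive values may be higher on the Mdr2-KO side, since the knocked-out gene stood at -10.76. The opposite direction would put the transcript of a knocked-out gene higher in the knockout. Only the wild-type group of the labels holds the intact gene. A comparison among knockout livers alone would hold no intact Abcb4 on either side, which the difference of -10.76 argues against. Which knockout livers were compared, and whether the reference held wild-type samples only, stays open.

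Called Coding peaks were mostly positive and called Proximal peaks mostly negative. The tables argue against tag depth as the whole cause, since the odds ratio of Coding against Proximal was 3.48 with 1000 or more tags. For the 699 of 1308 called Proximal peaks inside a gene, several peaks in the same gene do not account for it either. With 1 Proximal peak each, 43.6% of host genes were positive, below the Coding interval. The called Proximal peaks outside such genes, 38.8% of them positive, were not reduced in this way. Leaving out peaks in repeated sequence kept 1279 of the 1308 called Proximal peaks, of which 40.0% were positive. So few were left out that the share could hardly move, so it cannot decide on repeated sequence as a cause. Among peaks with 50 or more tags, negative Proximal peaks lay in repeats more often than uncalled ones (3.48% against 0.482%). So did negative Coding peaks (1.99% against 0.0793%), so this was not particular to the Proximal class. Called Proximal peaks inside a gene shared the sign of its main peak in 87.3% of 699 cases, and no biological explanation was tested.

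Called Distal peaks were more often positive than Proximal ones, and repeat-derived promoters were tried as a hypothesis. Among peaks with 50 or more tags, positive Distal peaks lay in repeated sequence less often than uncalled ones (Fisher's exact test, odds ratio 0.534, adjusted p = 0.020). These sets were not matched on tags, and how reads of repeated sequence were placed is not given in the sources used here. The comparison therefore cannot decide on high-copy repeats as the source, and older, diverged copies would be missed by exact 20-mers. Primer binding sites of 5 tRNA types, with up to 3 mismatches, followed 18 called Distal peaks of both signs, too few to compare. The site sequences were written from general knowledge and not checked.

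Sex makeup may differ between the groups compared, since the labels give females only among lesion-bearing samples. The lowest share of males in a group of the labels, 11 of 16, would take a gene that females lack to -0.54 at most. That holds if the authors' difference is a ratio of group means. Below it lay 12 of 14 male-biased genes, 9 of them called, with a median of -2.64 (quartiles -3.43 and -1.15). The 4 Y-linked genes, which females lack, also lay below it, from -1.43 to -0.84, and none passed. So the bound cannot decide whether the makeup of the groups is the cause for the male-biased genes. Neither the groups compared nor how the difference was formed is given in the sources used here. The Y-linked genes, taken as a bound on such a fall, leave it open, since their approximate lower 95% bounds reach from -2.31 to -3.32. For the female-biased genes neither Xist (adjusted p = 0.595) nor a Y-linked gene passed, so that a difference in sex cannot be told apart from a change of expression, and sex of the animals remains an untested biological explanation.

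Peaks with an absolute difference of 8 or more and an adjusted p under 0.05 numbered 287 positive and 44 negative, of which 158 and 25 were Distal. Sequence of another strain carried along with the knockout could give such peaks near Abcb4. Within 10 Mb of it 19 of 223 peaks were called, against 4072 of 48872 elsewhere (odds ratio 1.02, 95% interval 0.604 to 1.64, Fisher's exact p = 0.90). No excess was detectable there, although the interval is wide. Of the 330 large differences outside Abcb4 itself 329 lay beyond 10 Mb, and 95.8% (95% Wilson interval 93.0 to 97.5) were on other chromosomes, which argues against sequence linked to Abcb4 as the source of most of them, while a strain difference spread over the genome was not tested.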
